A study of Mus musculus with 10 samples.

How the data were processed

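Right atria of Lats1/2 CKO and control mice were profiled as nuclei in 6 RNA libraries and 4 ATAC libraries, the latter from the same nuclei as the multiome RNA. GW2580 was given by gavage from the first day of tamoxifen until the hearts were taken, and each library pooled tissue of both sexes, per the labels; how many mice a pool held is not given in the sources used here. Library preparation used a 10x Multiome kit and sequencing a Illumina NovaSeq instrument, per the labels. The deposited matrices hold raw counts: UMIs per gene and nucleus, and transposase cut sites per peak and nucleus for the multiome libraries, most of which are even numbers because a fragment has a pair of cut sites. The deposited names of genes, peaks and nuclei are other files without a measurement. The multiome matrices were made with Cell Ranger ARC 2.0.2 per the file headers, and the snRNA only matrices with Cell Ranger 7.1.0 per the file headers, where the submitters' processing notes name ARC 2.0.2 and mm10 for all. Nuclei had already been selected in the deposited matrices, and peaks had been called for each library separately, since the peak lists differ. Each matrix has 32291 genes. Gene positions came from a RefSeq table for GRCm38.p6, and 85.9% of 26316 shared symbols have their start within 2500 bp of the position in the matrices.

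Nuclei with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored against 2 simulated doublets per nucleus, and in each library the nuclei with the highest scores were left out, at an expected rate of 0.8% per 1000 nuclei. Of 31 clusters of a first round of clustering, 4 with over 50% of such nuclei were also left out. The CKO libraries kept 4479 (vehicle), 11043 (inhibitor multiome) and 8084 (inhibitor snRNA only) nuclei and the control libraries 1981, 11116 and 8216. All libraries were clustered together without batch correction (igraph 0.11.9, leidenalg 0.10.2; 3000 variable genes, 40 principal components, 20 neighbours, resolution 0.4), giving 19 clusters, of which 18 were named by marker lists and 1, of cycling cells, was left unnamed. A cluster was named where its best marker score led the next by 0.05. The resolution and this margin were chosen after looking at the clusters, before any comparison of groups. Naming nuclei in each library on its own gave the same class for 84.38% of nuclei and serves as an alternative. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

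The library was the replicate. Raw UMIs were summed over the nuclei of a class in each library, for classes with at least 20 nuclei in every library, and tested with the edgeR quasi-likelihood test (TMM scaling, filterByExpr) with terms for stratum and genotype, which leaves 2 residual degrees of freedom. Fibroblast sums ran from 1809408 UMIs (565 control vehicle nuclei) to 8927523, and macrophage sums from 322763 UMIs (95 control snRNA only nuclei) to 3732042. The inhibitor comparison is the contrast of inhibitor and vehicle multiome strata in the same fit, and the interaction a fit with 1 mean per genotype and treatment plus assay. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. With 1 library per arm and pooled animals, the spread behind these p-values may be mainly technical and need not hold over animals. On simulated data made from the fibroblast counts (15729 genes, 200 of them changed), the fit called 76% of genes changed by a factor of 2 and 100% of those changed by a factor of 4, with 1.7% false among its calls; for macrophages (10748 genes) this was 44%, 86% and 1.5%, and for regions (35364) 72%, 100% and 5.5%. The simulated counts had 1 preset spread for all genes or regions and no differences between strata, pools or sexes. These shares therefore check the fit and are not those of the real comparisons. Gene lists were tested with limma camera (preset correlation 0.01), with an estimated correlation and with fry, adjusted over the lists of a class. Shares of nuclei were compared by exact permutation of genotype within strata (8 arrangements, smallest two-sided p 0.25).

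Peaks of the 4 libraries were merged into 109775 regions, 35984 of which had a peak in every library; 35364 passed the count filter and were tested with edgeR on fibroblast cut sites, with terms for treatment and genotype (1 residual degree of freedom). The libraries had 91203 (CKO inhibitor), 69474 (CKO vehicle), 69013 (control inhibitor) and 46815 (control vehicle) peaks covering 83392003, 60975764, 62881375 and 41389147 bp, and 185 peaks off the standard chromosomes were left out. Regions called in both CKO libraries and no control library numbered 8975, and 688 the reverse; these were not tested. Transcription factor motifs were not analysed here.

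Before the data were examined, the tests, the gene lists, the alternatives and the rule for named genes were fixed. The rule names Lats1, Lats2, Yap1, Wwtr1, Tcf21, Csf1 and Csf1r always, then the 10 largest rises and 10 largest falls among called genes with the same direction in 3 strata and a mean of at least 10 CPM (5 each way for the inhibitor), leaving out gene models without an assigned name and genes under 0.1 of their level in another class, then up to 4 members of each list by smallest p. For classes other than fibroblasts the text names the first 5 each way. Some of the genes and regions that this rule names are not reported here. Regions were named by the starts of these genes and by the 5 largest changes each way. For each gene the nearest and next nearest region within 50000 bp were considered, and the region with the smaller p was named. A gene with 0 counts in a group is given as a lower bound against 3 counts over the group, and a gene with 1 to 3 counts by the ratio of counts with its 95% interval. Intervals and bounds cover counting error only. For regions they take each cut site as an independent count, though a fragment has a pair of cut sites. Intervals of regions are therefore too narrow, and their lower bounds too high, even for counting error. Free RNA in droplets gives low counts of genes of other classes, and genes under 0.1 of their level in another class are named as such. Alternatives were another test and scaling (DESeq2), no filter on low counts, doublets kept, at least 1000 genes per nucleus, classes clustered per library, equal nuclei per library, genes of free RNA left out, no stratum term, inhibitor libraries alone, multiome libraries alone and each library left out in turn. Added after seeing the data were nuclei of 1 sex alone, cluster 7 or 15 left out, regions of like covered length and the regions without each library and the treatment term.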

Results

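Single-nucleus RNA was measured in 6 libraries of mouse right atrium, and chromatin accessibility (ATAC, counted as transposase cut sites) in the same nuclei of 4 of them. In the conditional knockout (CKO), the tamoxifen-inducible line Tcf21iCre acted on floxed alleles of Lats1 and Lats2, the Hippo pathway kinases that restrain the coactivators Yap1 and Wwtr1. Control mice carried the floxed alleles without the Cre, and mice of both genotypes carried the nuclear envelope reporter Rosa26_Sun1GFP. Mice received vehicle or GW2580, a small-molecule inhibitor of Csf1r, at 80 ug/g. Csf1r is the receptor through which Csf1 keeps macrophages alive. Each library was a pool of male and female mice of about 9 weeks. The libraries form 3 strata of 1 CKO and 1 control library each: vehicle multiome, inhibitor multiome and inhibitor snRNA only. ATAC counts belong to the multiome strata.

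The CKO libraries held 4912 (vehicle multiome), 12977 (inhibitor multiome) and 9167 (inhibitor snRNA only) nuclei with 21528125, 50735736 and 49239688 RNA UMIs. The control libraries held 2146, 12940 and 9109 nuclei with 8697891, 38992297 and 33392667 UMIs, in the same order. Median depth over the nuclei that passed the filters was 3308, 2884.5 and 4303 UMIs per nucleus in the CKO and 3317, 2401 and 3129 in the control libraries. Among the nuclei whose sex could be called from Xist and Y-linked genes, 64.1%, 55.9% and 60.3% of CKO fibroblasts were male in those strata. In control fibroblasts the male shares were 29.2%, 29.9% and 36.7%. In macrophages, male nuclei made up 76.6%, 71.3% and 75.8% of the CKO and 30.2%, 20.7% and 33.8% of the control calls. The sex mix of the pools therefore moved with genotype in every stratum. For fibroblasts, macrophages, cardiomyocytes and vascular endothelial nuclei the genotype comparison of RNA was also run in male nuclei alone and in female nuclei alone. The other comparisons were not.

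The deletion was looked for first, in fibroblast RNA, in every library. Lats1 (ENSMUSG00000040021; mm10 chromosome 10, 7681200 to 7716461) had 76.9 CPM (UMIs scaled to equal library totals) in CKO and 91.5 in control fibroblasts with vehicle. It had 92.1 and 104 CPM with inhibitor in the multiome libraries, and 75.7 and 83.5 in the snRNA only libraries. Its log2 change of -0.18 (SE 0.09, n = 3 libraries per genotype, edgeR adjusted p = 0.116) did not pass the test. Lats2 (ENSMUSG00000021959; chromosome 14, 57689662 to 57746212) was higher in CKO, with a log2 change of 1.39 (SE 0.10, adjusted p = 1.49e-07). It stood at 378 against 122 CPM with vehicle, 327 against 140 with inhibitor in the multiome libraries and 270 against 106 in the snRNA only libraries. These are counts over the whole gene, not split by the deleted part, so they do not check the recombination. Fibroblast cluster 7 had 0 control nuclei and held 27.5% to 31.5% of the CKO fibroblasts. With it left out, the log2 change of Lats2 was -0.04 (adjusted p = 0.844).

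Macrophages took a larger share of nuclei in CKO than in control atria, and fibroblasts a smaller share, in all 3 strata. With vehicle, macrophages were 19.5% of CKO nuclei (exact Clopper-Pearson 95% interval 18.4% to 20.7%) and 6.56% of control nuclei (5.51% to 7.74%). With inhibitor they were 5.02% (4.62% to 5.44%) against 1.37% (1.16% to 1.60%) in the multiome libraries and 4.91% (4.45% to 5.41%) against 1.16% (0.936% to 1.41%) in the snRNA only libraries. The mean over libraries was 9.82% ± 8.41 (SD, n = 3) in CKO and 3.03% ± 3.06 in control. The difference within strata averaged 6.79 percentage points (SD 5.35). Its two-sided exact permutation p was 0.25, the smallest these 3 pairs allow. Without either vehicle library the difference was 3.70 points. Fibroblasts made up 18.4% ± 0.52 of CKO and 28.5% ± 1.05 of control nuclei, a difference within strata of -10.1 points (SD 1.39, n = 3 pairs, exact permutation p = 0.25). T and NK cells (0.774 points) and monocytes with dendritic cells (0.345 points) were also higher in CKO in 3 of 3 strata, and pericytes lower (-0.078 points), each with an exact permutation p of 0.25. Cardiomyocytes (1.60), endocardial cells (1.05), vascular endothelial cells (-0.774), mesothelial cells (0.28) and B cells (0.022) did not keep 1 direction over the strata. The intervals cover counting error only.

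The inhibitor was given to lower Csf1r signalling, and macrophages were the class it was aimed at. In the multiome libraries the macrophage share was 14.5 percentage points lower with inhibitor than with vehicle in CKO atria (3.89 times lower) and 5.20 points lower in control atria (4.80 times lower). These are single libraries per arm, so this difference was not tested.

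**Figure D1:**
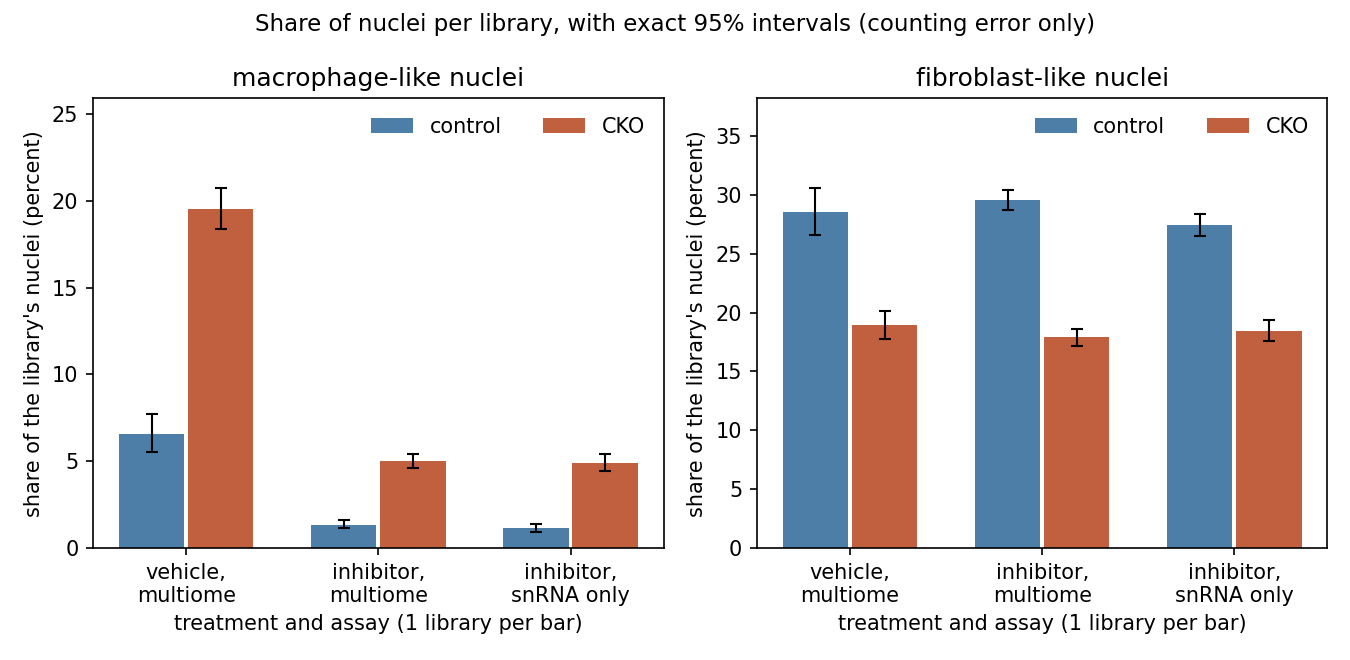
Share of nuclei (percent) called macrophages and fibroblasts in each of the 6 libraries, with control in blue and CKO in orange. Bars are single libraries and error lines their exact 95% intervals. The macrophage share ran from 1.16% (control, inhibitor, snRNA only) to 19.5% (CKO, vehicle), and the CKO bar was above the control bar in 3 of 3 strata.

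The comparison of CKO with control fibroblasts asks what differs between the genotypes in the class that the Cre targets. Of 15729 genes tested, 3768 were higher and 3578 lower in CKO (7346 in all, edgeR adjusted p under 0.05, 3 libraries per genotype). Several transcripts were nearly absent from control and present in CKO fibroblasts. Igfbp2 (ENSMUSG00000039323; chromosome 1, 72824480 to 72852474), which encodes a binding protein of insulin-like growth factors, had 2292 UMIs in CKO and 0 in control fibroblasts. This is at least 578-fold higher, against a floor of 3 counts over the group. Cemip, a hyaluronan-degrading protein, reached 196 ± 61.2 CPM against 0.279 ± 0.242 (log2 change 9.13, SE 0.20), and the squamous epithelial gene Scel 466 ± 44.8 against 0.84 ± 0.844 (8.71, SE 0.22). The kinesin gene Kif26b reached 509 ± 35.0 against 2.23 ± 0.631 (7.96, SE 0.17) and the cytokine gene Il6 59.6 ± 25.1 against 0.466 ± 0.58 (7.99, SE 0.35). Hs6st2 (7.85), Ctnnd2 (7.85) and Stac (7.78) followed. Cntn2 had 490 against 2 UMIs (ratio 185, counting interval 51.1 to 1536), and Col2a1 420 against 0. The largest falls were in the enkephalin precursor gene Penk (4.23 ± 2.55 against 77.7 ± 13.8 CPM, log2 change -4.31, SE 0.22), Myoc (-4.07), Adamts19 (-3.61) and the transcription factor gene Zbtb16 (-3.55, SE 0.16). They were followed by Fosb (-3.54), Aox3 (-3.28), Tmem52 (-3.14), Grm7 (-3.08), the adhesion gene Negr1 (1675 ± 208 to 199 ± 15 CPM, -3.07) and Stk32b (-2.94). Csf1 (ENSMUSG00000014599; chromosome 3, 107741048 to 107760469), the macrophage growth factor that binds the receptor GW2580 inhibits, rose from 115 ± 9.68 to 313 ± 40.7 CPM (log2 change 1.42, SE 0.10, adjusted p = 7.36e-08). Its receptor gene Csf1r (2.23, adjusted p = 0.000295) had over 10 times higher levels in macrophages, whose free RNA gives UMIs in other nuclei. Tcf21, the driver gene of the Cre, fell by 0.42 (SE 0.09, adjusted p = 0.00181). Yap1 (-0.19, adjusted p = 0.0932) and Wwtr1 (-0.01, adjusted p = 0.94) did not pass.

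Gene lists fixed before the data were examined moved in different directions in CKO fibroblasts. Matrix genes had 20 members higher and 2 lower of 24 (camera adjusted p = 9.27e-07, adjusted p = 0.205 with an estimated correlation). Among them were the collagen gene Col12a1 (18.8 ± 0.381 to 524 ± 85.5 CPM, log2 change 4.84), the fibronectin gene Fn1 (89.5 ± 13.2 to 1094 ± 47.0 CPM, 3.60), Cthrc1 (6.32) and the collagen cross-linking enzyme gene Lox (4.48). Contractile genes rose in 12 of 13 and fell in 1 (camera adjusted p = 1e-05, adjusted p = 0.205 with an estimated correlation). The smooth muscle actin gene Acta2 was at 218 ± 60.9 against 3.21 ± 0.797 CPM (5.97), beside Tagln (4.02), Actn1 (3.02) and Cald1 (2.75). Genes of resident fibroblasts had 14 members lower and 1 higher of 17 (camera adjusted p = 8.28e-06, adjusted p = 0.233 with an estimated correlation). Dpep1 went from 911 ± 15.4 to 126 ± 7.84 CPM (-2.85) and the actin-severing gene Gsn from 13557 ± 2676 to 2108 ± 554 CPM (-2.71). Abca8b (-1.57) and Lpl (-1.77), which is over 10 times higher in another class, fell too. Cytokine genes had 11 members higher and 2 lower of 15 (camera adjusted p = 0.000172, adjusted p = 0.205 with an estimated correlation). These include the monocyte-attracting chemokines Ccl7 (6.24, SE 0.25) and Ccl2 (8.05 to 79.5 CPM, 3.30). Targets of Yap1 and Wwtr1 had 15 members higher and 6 lower of 23 (camera adjusted p = 0.0158, adjusted p = 0.24 with an estimated correlation). Amotl2 rose from 32.9 ± 7.04 to 310 ± 16.9 CPM (3.19), Ccn1 from 42.6 ± 11.5 to 356 ± 78.5 (3.14), Crim1 by 2.28 and Tgfb2 by 1.91. Cell cycle genes rose in 18 of 18 (camera adjusted p = 2.14e-11, adjusted p = 0.233 with an estimated correlation), among them Cdk1 (6.56), Ect2 (5.62), Cenpe (5.60) and Tpx2 (5.59). Fibroblast cluster 16, with Neil3, Top2a, Prc1 and Aspm among its 10 top genes, held 74 CKO and 2 control nuclei. Adjusted over the list alone, the counts were 15 and 7 for the Yap1 and Wwtr1 targets, 12 and 2 for the cytokines, and those given above for the rest.

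Lists of cartilage and bone genes were fixed because the series names osteochondroprogenitors. Of 12 chondrocyte genes tested, 4 were higher and 4 lower. The camera adjusted p was 0.748 (0.829 with an estimated correlation), with a median log2 change of -0.14 beside a mean of 1.87 and a test pointing up. The members that rose include the cartilage collagen genes Col2a1 (420 against 0 UMIs, at least 106-fold higher) and Col11a1 (2.93 ± 0.968 to 211 ± 53.8 CPM, log2 change 6.28, SE 0.15) and the cartilage proteoglycan gene Acan (391 against 0 UMIs, at least 98.7-fold higher). Of 10 osteoblast genes, 5 were higher and 1 lower (camera adjusted p = 0.146, 0.475 with an estimated correlation). Tnfrsf11b, which encodes the decoy receptor that limits osteoclast formation, rose by 5.23 (SE 0.19) and the phosphatase gene Alpl by 1.66 (SE 0.28). Runx2, the transcription factor of bone-forming cells, rose by 1.23, though with levels over 10 times higher in another class. The osteopontin gene Spp1 had 437 UMIs in CKO and 0 in control fibroblasts (at least 110-fold higher). It was at 33.9 and 19.5 CPM in the CKO inhibitor libraries and 0.23 in the CKO vehicle library, and its DESeq2 adjusted p was 0.0671. Adjusted over the list alone, both lists kept these counts.

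Of the other fibroblast lists, interferon genes had 9 members higher and 1 lower of 14 (camera adjusted p = 0.00358, adjusted p = 0.233 with an estimated correlation), with Cxcl10 (3.21), Rsad2 (2.72) and Ifi44 (2.39). TGF-beta and BMP genes had 10 higher and 4 lower of 18 (camera adjusted p = 0.0448, adjusted p = 0.369 with an estimated correlation). They include Bmp6 (2.79) and Bmp4 (1.94), which were higher. Immediate early and heat shock genes had 8 members lower and 0 higher of 13 (camera adjusted p = 0.0221, adjusted p = 0.233 with an estimated correlation), among them Nr4a1 (-1.30), Btg2 (-1.25) and Egr1 (-0.95). Wnt genes went both ways (4 higher, 4 lower of 12, camera adjusted p = 0.748, 0.845 with an estimated correlation). Sfrp2 (0.58) was higher and Dkk3 (-1.76), Axin2 (-1.19) and Wnt5a (-1.13) lower. The test pointed down (mean -0.06) beside a median of 0.03. Adjusted over the list alone, interferon genes had 11 higher and 1 lower, and the other 3 lists kept their counts. No camera call in any class held with an estimated correlation.

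**Figure D2:**
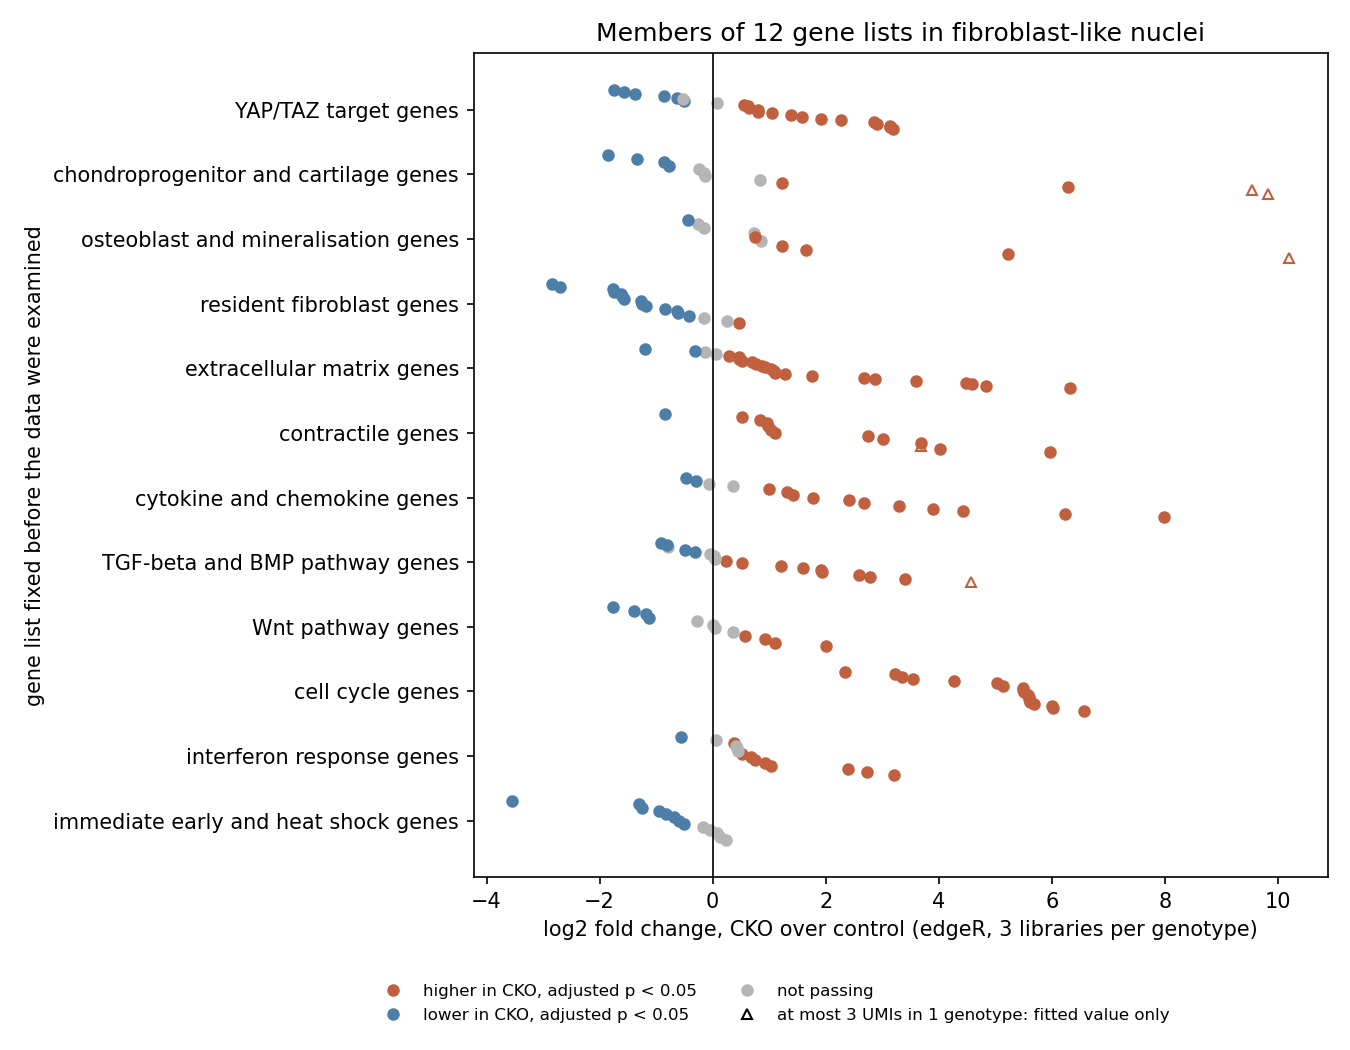
Log2 change between CKO and control fibroblasts for each tested member of 12 gene lists, with each point 1 gene. Orange and blue points are higher and lower in CKO at an edgeR adjusted p under 0.05, grey points did not pass, and open triangles had 3 or fewer UMIs in 1 genotype, so that their fitted value is no measured fold. All 18 cell cycle genes lie above 0, and 14 of 17 resident fibroblast genes are blue.

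Without the CKO inhibitor multiome library 4500 fibroblast genes passed, and with cluster 7 left out 3240 passed. Without cluster 7 the genes called with all nuclei had a median log2 change of 0.41 in the direction of their call. With all nuclei the median of the same genes was 0.76. Cemip, Col11a1, Col12a1, Hs6st2 and Ctnnd2 are among the 10 top genes of cluster 7. Its nuclei had 2.26 times the median UMIs of their library, as a median over nuclei. Leaving out cluster 7 ended the calls of Amotl2 (log2 change 0.20, adjusted p = 0.288), Crim1 (0.25, 0.324), Bmp4 (-0.16, 0.326), Egr1 (-0.28, 0.0885) and Sfrp2 (0.26, 0.14) and turned those of Csf1 (-0.28, 0.0464) and Bmp6 (-0.53, 0.0249). In male nuclei alone 5431 genes passed and Btg2 (adjusted p = 0.54), Egr1 (0.814), Nr4a1 (0.235) and Sfrp2 (0.0564) did not. In female nuclei alone 2221 passed and Axin2 (0.124), Runx2 (0.764), Tcf21 (0.753) and Wnt5a (0.117) did not. Of 67 named fibroblast genes, 24 had a log2 change that differed between male and female nuclei (edgeR interaction adjusted p under 0.05), 21 of them with the larger change in male nuclei. Among them were Dpep1 (-3.36 in male and -1.80 in female nuclei), Abca8b (-2.26 and -0.57), Gsn (-3.19 and -1.65), Adamts19 (-4.52 and -2.28) and Fn1 (3.85 and 2.53). Fosb, named above among the largest falls, was at -4.33 in female nuclei and had too few counts to be tested in male nuclei alone. Its log2 change was higher in male than in female nuclei by 5.05 (SE 1.33, edgeR interaction adjusted p = 0.0238). DESeq2 called 4797 genes, and a draw of equal nuclei per library 4672, in which Tcf21 did not pass (adjusted p = 0.0796). Without the stratum term Tcf21 (0.109) and Sfrp2 (0.203) did not pass.

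The inhibitor comparison asks which fibroblast genes differ between GW2580 and vehicle, within genotype, in the multiome libraries. Of the genes tested, 54 were higher and 31 lower with inhibitor (85 in all, edgeR adjusted p under 0.05). Immediate early and heat shock genes had 5 members higher and 0 lower of 13 (camera adjusted p = 7.29e-07, adjusted p = 0.349 with an estimated correlation; 8 and 0 adjusted over the list alone). Among them were Fosb (log2 change 2.90, SE 0.48), Fos (1.37), Btg2 (0.80) and Egr1 (0.76). Egr3 (1.86), which is not in the list, was also higher. The metallothionein gene Mt2 rose from 17.1 ± 8.12 to 63.0 ± 4.68 CPM (2.00, SE 0.19, adjusted p = 0.000652). Ch25h (2.37), Tnc (1.47), Col24a1 (1.73), Ly6a (0.96) and Thbs1 (0.79) also rose. Hmga2, which encodes a chromatin protein of growing cells, fell by 3.42 (SE 0.27, adjusted p = 0.000144). Col2a1 (-2.35), Slc35f1 (-2.06), the cyclin gene Ccnd1 (-1.51), the growth factor gene Nrg1 (-1.42, SE 0.14) and Ccl2 (-1.04) fell with it. Matrix genes had 2 members higher of 24 (camera adjusted p = 0.0148, adjusted p = 0.538 with an estimated correlation; 4 adjusted over the list alone). Resident fibroblast genes had 1 higher of 17 (camera adjusted p = 0.0149, adjusted p = 0.716 with an estimated correlation; 5 adjusted over the list alone). Cell cycle genes pointed down by camera (adjusted p = 0.000418, adjusted p = 0.716 with an estimated correlation). Their median was -0.06, and 0 of 18 members passed in edgeR over all genes or adjusted over the list alone.

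None of the other 8 lists was called by camera for the inhibitor. Among the Yap1 and Wwtr1 targets 0 of 23 members passed in edgeR (camera adjusted p = 0.902). The cytokine list had 2 higher and 2 lower of 15 (adjusted p = 0.535; 7 and 3 adjusted over the list alone) and TGF-beta and BMP genes 1 higher of 18 (adjusted p = 0.0981; 2 higher and 2 lower adjusted over the list alone). Osteoblast genes had 1 higher of 10 (adjusted p = 0.921; 4 adjusted over the list alone) and chondrocyte genes 1 lower of 12 (adjusted p = 0.902; 1 higher and 1 lower adjusted over the list alone). Contractile, Wnt and interferon genes had 0 called in edgeR over all genes (camera adjusted p = 0.902 for each), and adjusted over the list alone 1 Wnt gene was higher. The test pointed down for the Yap1 and Wwtr1 targets (median 0.037) and the osteoblast genes (median 0.126) and up for the interferon genes (median -0.042), against the sign of these medians. Lats1, Lats2, Yap1, Wwtr1, Tcf21, Csf1 and Csf1r did not pass (adjusted p from 0.452 to 0.977). This comparison rests on 4 libraries and mostly on those of CKO mice. Without the CKO inhibitor multiome library edgeR called 0 genes (615 at an unadjusted p under 0.05), and all 17 named genes that passed were lost (adjusted p from 0.0755 to 1). Without the CKO vehicle library 138 genes passed but 12 of the 17 were lost (0.0968 to 1), Hmga2 and Col2a1 changing sign. Without the control inhibitor multiome library 4 were lost (Fosb 0.507, Egr3 0.212, Btg2 0.206, Thbs1 0.0904). Without the control vehicle library Fosb was (0.429), with 594 genes called. The counts were 178 without the CKO and 251 without the control snRNA only library. They were 31 by DESeq2, 41 with DESeq2 size factors, 341 with no filter on low counts, 144 with doublets kept, 35 with nuclei of at least 1000 genes and 3 with equal nuclei per library. Of the named genes, DESeq2 lost 10 of 17 (adjusted p from 0.0669 to 1) and equal nuclei 14 of 16 (0.126 to 0.896). Nuclei of at least 1000 genes lost Fosb, Fos, Btg2, Egr1 and Thbs1 (0.0513 to 0.0836), DESeq2 size factors Ch25h, Fos, Btg2 and Egr1 (0.0508 to 0.0613), and doublets kept Egr1, Ccl2 and Tnc (0.0555 to 0.122).

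Whether the inhibitor changed the difference between CKO and control fibroblasts was tested as an interaction, over 16592 genes. The signed log2 difference (CKO minus control) was higher with inhibitor for 150 genes and lower for 135 (edgeR adjusted p under 0.05, 1 residual degree of freedom). Each vehicle library was assumed to vary like the inhibitor libraries. For a gene that is lower in CKO, a higher signed difference can mean a smaller gap between the genotypes. Among the Yap1 and Wwtr1 targets 3 of 23 had a higher signed difference, Ccn2 (log2 0.96, adjusted p = 0.00213), Ankrd1 (0.88, 0.0271) and Ccn1 (0.85, 0.0487). Adjusted over the list alone, 3 were higher and 1 lower. No other list had more than 2 members called over all genes, and no test of a whole list was run. Alpl (2.36, 3.61e-05), the protease inhibitor gene Timp1 (1.13), the chemokine gene Cxcl5 (1.82) and the alarmin gene Il33 (1.14) also had a higher signed difference. The signed difference was lower for the sterol enzyme gene Cyp51 (-3.86), the receptor gene Met (-7.93, SE 2.04), S100a4 (-2.34, SE 0.34, adjusted p = 8.05e-08), Cd109 (-2.65), Gpr176 (-2.64) and the interferon gene Isg15 (-2.30). The cell cycle genes Neil3 (4.72), Kif14 (3.67), Kif4 (3.65), Top2a (3.49, SE 0.51) and Mki67 (2.86), with Fam163b (2.94), had the largest positive values. Top2a stood at 12.3 CPM in the control vehicle library against 0.56 and 1.69 in the other control libraries. Cluster 16, with Neil3 and Top2a among its top genes, held 1 of the 565 fibroblasts of the control vehicle library. It held 0 nuclei of the control inhibitor multiome and 1 of the control snRNA only library. Whether the control vehicle library, or its 1 nucleus of cluster 16, drives the values of these genes was not tested. With classes clustered per library Top2a (0.73, adjusted p = 0.862), Kif14 (0.619), Kif4 (0.847), Neil3 (0.835) and Mki67 (0.583) did not pass. These are among 8 of the 19 named genes that lost their call in that setting. DESeq2 called 51 genes and lost 13 of the 19, and equal nuclei gave 163 and lost 7. Among the targets, Ccn2 (adjusted p = 0.0519), Ankrd1 (0.615) and Ccn1 (0.0838) were lost with equal nuclei, and Ankrd1 (0.485) and Ccn1 (0.384) with DESeq2. Ccn1 was also lost with DESeq2 size factors (0.0533), nuclei of at least 1000 genes (0.125) and classes clustered per library (0.0854). Lats1, Lats2, Yap1, Wwtr1, Tcf21, Csf1 and Csf1r did not pass (adjusted p from 0.554 to 0.979).

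In macrophages, which were not the target of the Cre, 698 genes were higher and 621 lower in CKO of 10748 tested (1319 in all, edgeR adjusted p under 0.05, 3 libraries per genotype). Genes of resident cardiac macrophages had 8 members lower and 0 higher of 11 (camera adjusted p = 1.16e-07, adjusted p = 0.314 with an estimated correlation; 11 lower adjusted over the list alone). The scavenger receptor gene Cd163 went from 1504 ± 78.9 to 458 ± 91.1 CPM (log2 change -1.74, SE 0.14) and F13a1 from 1963 ± 705 to 709 ± 187 (-1.44). The complement receptor gene Vsig4 went from 1273 ± 137 to 553 ± 31.6 (-1.20), and Igf1 fell by 1.47. Monocyte and antigen presentation genes had 6 members higher of 12 (camera adjusted p = 7.86e-05, adjusted p = 0.343 with an estimated correlation; 7 adjusted over the list alone). The chemokine receptor gene Ccr2 was at 543 ± 203 against 117 ± 86.6 CPM (2.31, SE 0.21), and Plac8 (2.96) and Itgax (2.37) rose too. Cell cycle genes had 15 higher of 17 (camera adjusted p = 3.37e-11, adjusted p = 0.314 with an estimated correlation; 17 adjusted over the list alone). Kif11 (2.88), Top2a (2.11) and Mki67 (1.75) were among them. Osteoclast genes had 4 higher of 6 (camera adjusted p = 0.0046, adjusted p = 0.343 with an estimated correlation; 4 adjusted over the list alone), among them the fusion gene Dcstamp (2.71, SE 0.55) and the phosphatase gene Acp5 (1.60, SE 0.30). Interferon genes had 3 higher of 13 (camera adjusted p = 0.000497, adjusted p = 0.445 with an estimated correlation; 5 adjusted over the list alone). Cxcl10 had 255 against 1 UMI (ratio 37.0, 6.58 to 1467).

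Lipid-handling genes went both ways in macrophages (3 higher, 1 lower of 12, camera adjusted p = 0.194, 0.571 with an estimated correlation, the same counts adjusted over the list alone). Apoe fell from 5761 ± 1575 to 2110 ± 674 CPM (-1.48), Lgals3 rose (0.82) and Mmp12 had 224 against 3 UMIs (ratio 10.8, 3.66 to 52.9). Of the immediate early genes 0 of 10 passed in edgeR (camera adjusted p = 0.999 pointing down, median 0.04). Outside the lists, Chil3 (296 against 0 UMIs), Spint1 (299 against 0), Spp1 (171 against 0) and the vitamin D receptor gene Vdr (133 against 0) were at least 14.3, 14.5, 8.27 and 6.43 times higher in CKO. Uck2 had 426 against 2 UMIs (ratio 30.9, 8.50 to 256). The lipoxygenase gene Alox15 was at least 78.1-fold lower (0 against 34 UMIs), and Vmn2r26 had 2 against 41 UMIs (ratio 0.00708, 0.000829 to 0.0272). Eps8l1 (-4.57), Prg4 (-4.34, SE 0.53) and Cyp2ab1 (-4.32, SE 0.65) fell. Csf1r, the receptor that GW2580 inhibits, went from 846 ± 53.9 to 604 ± 54.6 CPM (log2 change -0.49, SE 0.14, adjusted p = 0.0337). Lats2 went from 148 ± 8.26 to 93.1 ± 7.31 (-0.67, SE 0.17, adjusted p = 0.0204). Lats1 (0.04, adjusted p = 0.928) and Wwtr1 (0.20, adjusted p = 0.791) did not pass. Wwtr1 and Csf1 (2.25, adjusted p = 0.0122, 159 against 5 UMIs) are over 10 times higher in another class. Yap1 and Tcf21 had too few counts to be tested.

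**Figure D3:**
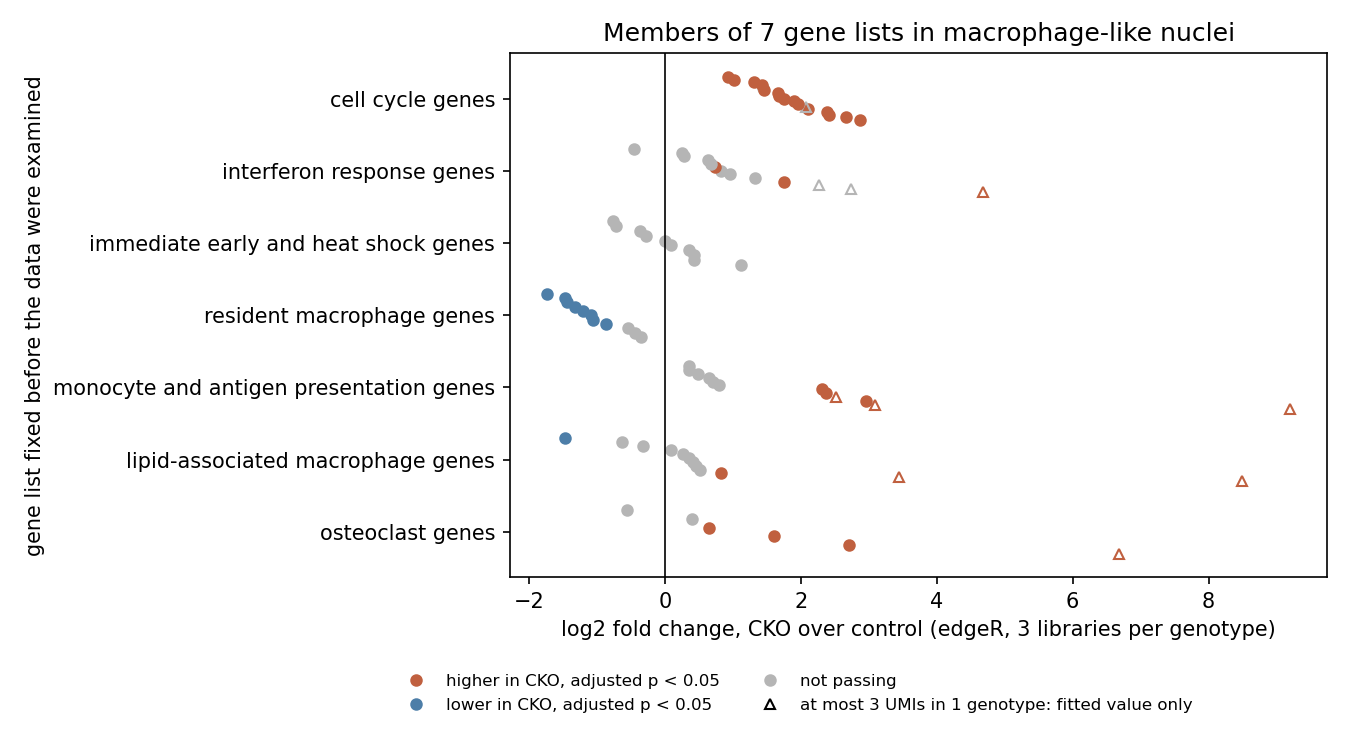
Log2 change between CKO and control macrophages for each tested member of 7 gene lists, with each point 1 gene. Orange and blue points are higher and lower in CKO at an edgeR adjusted p under 0.05, grey points did not pass, and open triangles had 3 or fewer UMIs in 1 genotype. Of 17 cell cycle genes 15 are called higher, and of 11 resident macrophage genes 8 are called lower.

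The macrophage calls moved with single libraries and with the definition of the class. Without the control inhibitor multiome library 827 genes passed and Lats2 (adjusted p = 0.0809), Csf1r (0.0726) and Lgals3 (0.0805) did not. Without the CKO snRNA only library 770 passed, and Lats2 (0.0956), Csf1r (0.235) and Lgals3 (0.076) did not. Without the control snRNA only library 650 passed, and Lats2 (0.135), Csf1 (0.0682), Csf1r (0.275), Vmn2r26 (0.0538) and Lgals3 (0.102) did not. Without the CKO inhibitor multiome library Csf1 (0.0847), Vdr (0.124), Eps8l1 (0.0623) and Lgals3 (0.05) did not pass, and without the control vehicle library Lats2 (0.0632) did not. With classes clustered per library 463 genes passed. The calls of Kif11 (log2 change 1.38, adjusted p = 0.316), Top2a (1.12, 0.316), Mki67 (0.78, 0.536), Cxcl10 (0.0676), Itgax (0.0735), Vsig4 (0.0564), Lats2 (0.193) and Vmn2r26 (0.0597) were lost. Csf1r was at 0.04 (adjusted p = 0.915) and Csf1 at 0.42 (0.688). Control macrophages called male numbered 32 (vehicle), 24 (inhibitor multiome) and 22 (snRNA only) nuclei, and those called female 74, 92 and 43. The tests by sex therefore rest on few counts. In male nuclei alone 222 genes passed, and 11 of 23 named genes that could be tested did not (adjusted p from 0.0549 to 0.65), among them Csf1r, Mki67, Plac8, Itgax and Dcstamp. In female nuclei alone 328 passed, and 4 of 16 named genes did not, Lats2 (0.208), Csf1r (0.298), Lgals3 (0.0884) and Acp5 (0.57). Of 25 named macrophage genes 0 differed between male and female nuclei by edgeR at an adjusted p under 0.05 (374 of all genes tested at an unadjusted p under 0.05). DESeq2 called 709, equal nuclei gave 833, no stratum term 684 and the multiome libraries alone 566. Of the named genes DESeq2 lost 7 of 27 (0.0539 to 0.326), among them Spp1, Alox15 and Vmn2r26. Equal nuclei lost 3 of 24 (0.071 to 0.285), no stratum term 4 of 23 (0.0523 to 0.23), the multiome libraries 6 of 23 (0.0505 to 0.251) and no filter Lats2 (0.0522) and Csf1r (0.0797).

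With inhibitor, 63 macrophage genes were higher and 13 lower than with vehicle (76 in all, edgeR adjusted p under 0.05, multiome libraries). The protease inhibitor gene Slpi had 150 against 3 UMIs (ratio 105, 35.2 to 515). The coagulation factor gene F10 rose by a log2 of 5.65 (SE 0.46, adjusted p = 0.000128), Thbs1 by 3.88 (SE 0.43), Spp1 by 3.55, Chil3 by 2.92, Ccr2 by 1.41 and Lgals3 by 1.27. Saa3 had 38 against 1 UMI (ratio 79.8, 13.5 to 3232) and Rab44 33 against 2 (ratio 34.6, 8.86 to 298). Cxcl10 (-2.56), Btbd11 (-1.95), Etv5 (-1.56), the chemokine receptor gene Cx3cr1 (-1.43), Pvt1 (-1.10) and the osteoclast receptor gene Tnfrsf11a (-0.87) fell. Lipid-handling genes had 2 members higher of 12 (camera adjusted p = 0.023, adjusted p = 0.842 with an estimated correlation; 6 adjusted over the list alone). Cell cycle genes pointed down (camera adjusted p = 2.03e-07, adjusted p = 0.842 with an estimated correlation). In this list 0 of 17 members were past the edgeR threshold over all genes and 8 lower adjusted over the list alone. The monocyte (2 higher, adjusted p = 0.349; 3 adjusted over the list alone), osteoclast (1 lower, adjusted p = 0.665, a test pointing down beside a median of 0.26), resident (adjusted p = 0.665; 2 higher and 2 lower adjusted over the list alone), interferon (1 lower, adjusted p = 0.665) and immediate early lists (adjusted p = 0.955) were not called. Without the CKO inhibitor multiome library camera called 1 list, and without the control vehicle library 6. Csf1r (-0.04, adjusted p = 0.987), Csf1, Lats1, Lats2 and Wwtr1 did not pass. Without the CKO inhibitor multiome library 47 genes passed and 10 of 14 named genes were lost (adjusted p from 0.189 to 1: Saa3, Rab44, Thbs1, Cxcl10, Btbd11, Etv5, Cx3cr1, Chil3, Lgals3 and Tnfrsf11a). Without the CKO vehicle library 158 passed and 8 were lost (0.175 to 1: Rab44, Thbs1, Btbd11, Cx3cr1, Chil3, Spp1, Lgals3 and Tnfrsf11a). Without the control vehicle library 378 passed. Saa3 was also lost without the control inhibitor multiome (0.349) or the CKO snRNA only library (0.0744), and Tnfrsf11a without those (0.0633 and 0.0628) or the control snRNA only library (0.0782). With classes clustered per library 1 gene passed, and F10 was the only named gene to keep its call. DESeq2 called 26, equal nuclei gave 44, no filter 208 and doublets kept 169.

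Cardiomyocytes had 435 genes higher and 192 lower in CKO of 12179 tested (627 in all, edgeR adjusted p under 0.05, 3 libraries per genotype). The channel gene Hcn4 (3.34 ± 4.53 to 32.2 ± 20.4 CPM, log2 change 3.10, SE 0.49) rose, as did the potassium channel gene Kcnq1 (0.57). In the list, 3 of 14 ion channel genes were higher and 0 lower (camera adjusted p = 0.291; 4 and 1 adjusted over the list alone). In the stress list 1 of 8 genes was higher, Ankrd1 (0.76), and 3 lower, the natriuretic peptide genes Nppb (-0.88) and Nppa (-0.71) and the myosin gene Myh7 (-1.10, SE 0.15), with a camera adjusted p of 0.291 (2 and 4 adjusted over the list alone). Junb (1.46, SE 0.23) was the member of the immediate early list to pass (1 of 10, camera adjusted p = 0.524; 1 higher and 2 lower adjusted over the list alone). Serpina3i had 247 UMIs in CKO and 0 in control (at least 44.7-fold higher) and Card14 rose by 4.55. Bfsp2 (-1.93), Krt7 (-1.82), Fxyd3 (-1.75), Zbtb16 (590 ± 64.6 to 194 ± 25 CPM, -1.59) and Rarres2 (-1.53) fell. Ptx3 (213 against 1 UMI), Igfbp2 (201 against 2) and Lox (5.23) were also higher. They stood at 22.1, 34.0 and 84.2 CPM in cardiomyocytes beside 232, 163 and 276 in fibroblasts of the CKO inhibitor multiome library. Csf1 (0.88, SE 0.21, adjusted p = 0.0209) passed, and Lats1, Lats2, Yap1, Wwtr1, Tcf21 and Csf1r did not (adjusted p from 0.225 to 0.646).

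Cardiomyocyte cluster 15 held 75 CKO and 6 control nuclei, and without it 467 genes passed, without Krt7 (adjusted p = 0.111) and Nppa (0.0544). The number of cardiomyocyte genes was 388 without the CKO inhibitor multiome, 367 without the CKO snRNA only, 1080 without the CKO vehicle and 1096 without the control vehicle library. Csf1 did not pass without the CKO (adjusted p = 0.197) or control inhibitor multiome library (0.186), or without the CKO (0.12) or control snRNA only library (0.0871). Krt7 (0.365 and 0.244) and Kcnq1 (0.257 and 0.188) did not pass without the CKO or control snRNA only library, nor did Ankrd1 without the CKO snRNA only library (0.0999). Nppa (0.442 and 0.413) and Kcnq1 (0.103 and 0.109) did not pass without the CKO or control vehicle library. In female nuclei alone 162 genes passed and Ankrd1 was lower (-0.66, adjusted p = 0.0373), while Junb (0.839), Myh7 (0.103), Kcnq1 (0.73), Csf1 (0.729) and Bfsp2 (0.0515) did not pass. In male nuclei alone 378 passed and Nppb (0.437), Nppa (0.0845), Csf1 (0.102) and Bfsp2 (0.0783) did not. Of 22 named cardiomyocyte genes, 3 differed between male and female nuclei: Ankrd1 (1.55 and -0.66), Nppb (-0.44 and -2.28) and Junb (2.61 and 0.34). DESeq2 called 294 genes, no filter gave 962, doublets kept 1092, and nuclei of at least 1000 genes 403. Equal nuclei gave 166, no stratum term 221, the inhibitor libraries alone 1100 and the multiome libraries alone 299. Of the named genes DESeq2 lost 4 of 18 (0.0765 to 0.429), nuclei of at least 1000 genes 5 of 18 (0.0542 to 0.138), equal nuclei 5 of 12 (0.127 to 0.427), no stratum term 7 of 17 (0.0893 to 0.336) and the multiome libraries 4 of 17 (0.146 to 0.469), with Csf1 and Kcnq1 lost in each. Classes clustered per library lost Fxyd3 (0.0859) and Rarres2 (0.113), and the inhibitor libraries Nppa (0.461) and Kcnq1 (0.106). With inhibitor against vehicle 1 cardiomyocyte gene passed, Spp1, named here after its value was seen (748 at an unadjusted p under 0.05). Immediate early genes were called up by camera (adjusted p = 0.000322, adjusted p = 0.675 with an estimated correlation; 2 adjusted over the list alone), and the stress (0.248) and ion channel lists (0.592) were not called.

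Vascular endothelial nuclei had 618 genes higher and 525 lower in CKO of 11421 tested (1143 in all, edgeR adjusted p under 0.05, 3 libraries per genotype). In the endothelial activation list 5 members were higher and 2 lower of 14 (camera adjusted p = 0.0143, adjusted p = 0.121 with an estimated correlation; the same counts adjusted over the list alone). The leukocyte adhesion genes Selp (36.6 ± 3.64 to 120 ± 13.2 CPM, log2 change 1.71, SE 0.17) and Sele (2.23, SE 0.25) and the basement membrane collagen genes Col4a2 (260 ± 2.93 to 678 ± 170, 1.41) and Col4a1 (1.33) rose. Zbtb16 fell from 366 ± 24.5 to 34.2 ± 11.2 CPM (-3.58, SE 0.17), and Eps8l1 (-3.05), Tmem255a (-2.52), Vwa3a (-2.17) and AI838599 (-2.13) fell. The activin subunit gene Inhbb (4.43, SE 0.58) and the mitotic genes Tpx2 (4.91) and Kif11 (4.15) rose, Aspm had 94 against 1 UMI (ratio 64.1, 11.2 to 2556) and Adamts4 110 against 3 (ratio 25, 8.33 to 123). Lats1, Lats2, Yap1, Wwtr1, Tcf21 and Csf1 did not pass (adjusted p from 0.422 to 0.874). With inhibitor against vehicle 19 genes were higher and 7 lower, with 1 of the activation genes passing (camera adjusted p = 0.729, pointing down beside a median of 0.026; 2 higher and 3 lower adjusted over the list alone).

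Vascular endothelial calls moved with the class definition. With classes clustered per library 339 genes passed, and the mitotic genes changed sign and did not pass (Aspm -0.17, adjusted p = 0.98; Tpx2 -0.52, 0.856; Kif11 -1.30, 0.606). In that setting nuclei otherwise named endocardial took the name, so that vascular endothelial nuclei were 27.2% of CKO and 5.41% of control nuclei, against 4.59% and 5.37% otherwise. Col4a1 (0.0971), Col4a2 (0.172) and AI838599 (0.122) did not pass either. The count was 379 without the CKO and 355 without the control inhibitor multiome library (AI838599 at an adjusted p of 0.0591 without the latter). It was 627 without the CKO and 639 without the control snRNA only library, and 1716 without the CKO vehicle library. In male nuclei alone 607 genes passed and in female nuclei alone 104, without Col4a1, Col4a2, Selp, Eps8l1, Tpx2, Vwa3a and AI838599 (adjusted p from 0.0569 to 0.57). Of 19 named genes, 2 differed between male and female nuclei, Col4a1 (1.92 and 0.31) and Col4a2 (1.69 and 0.50). DESeq2 called 377 and not Inhbb (0.128), equal nuclei gave 296 without Vwa3a (0.0561) and AI838599 (0.0796), no stratum term 461 and the multiome libraries alone 446.

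Accessibility was compared between CKO and control fibroblasts in 4 multiome libraries (2 per genotype), over 35364 regions with peaks in all of them. In the CKO inhibitor, CKO vehicle, control inhibitor and control vehicle libraries, fibroblasts had 12243527, 6045781, 9161288 and 1808844 cut sites in peaks. More accessible in CKO were 1963 regions and less accessible 2512 (4475 in all, edgeR adjusted p under 0.05, 1 residual degree of freedom). Scaled by library size, which shifts the median log2 change from 0.017 to 0.12, the split was 2494 and 1821. For each gene the region given had the smaller p of up to 2 nearest its start, so it need not be the nearest. The region named for Ankrd1, a target of Yap1 and Wwtr1 (mm10 chromosome 19, 36119573 to 36120991), opened by a log2 of 3.20 (SE 0.32, adjusted p = 3.17e-08). Regions near Amotl2 (chromosome 9, 102721706 to 102722633, 4904 bp away; 1.37, SE 0.30) and Il6 (chromosome 5, 30012666 to 30013648; 1.21, SE 0.20) also opened. So did regions near Actn1 (chromosome 12, 80259975 to 80261002; 1.04), Fn1 (chromosome 1, 71652716 to 71653739; 0.82) and Ccl2 (chromosome 11, 82032635 to 82033582; 0.62). Less accessible were regions at Dpep1 (chromosome 8, 123185490 to 123186557; -1.46, SE 0.15, adjusted p = 4.53e-08), Tcf21 (chromosome 10, 22819737 to 22820656; -0.71, SE 0.18) and Gsn (chromosome 2, 35264890 to 35265968; -0.70). The regions named for Lats1 (0.23, adjusted p = 0.598), Lats2 (0.44, 0.501), Yap1 (-0.40, 0.128), Wwtr1 (-0.25, 0.303), Csf1 (-0.07, 0.831) and Ccn1 (0.36, 0.172) did not pass. The region linked to Csf1r (0.99, SE 0.23, 0.00358) lies 46457 bp away, in Pdgfrb.

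Each list gene was counted by the region with the smaller p of up to 2 nearest, a choice that can raise the number called. Of all 35364 regions tested, 4475 were called. Counted by list, regions near resident fibroblast genes closed in 7 of 17 and opened in 0. Those near cytokine genes opened in 6 of 17 and closed in 0, and those near contractile genes opened in 4 of 14 and closed in 0. Immediate early genes had 4 of 13 regions closed and 0 opened, Yap1 and Wwtr1 targets 4 opened and 3 closed of 23, and matrix genes 4 and 5 of 21. For chondrocyte genes these numbers were 4 and 1 of 15, for osteoblast genes 1 and 2 of 15 and for TGF-beta and BMP genes 2 and 2 of 17. Wnt genes had 1 and 3 of 13, cell cycle genes 3 and 1 of 18, and interferon genes 0 of 13 by edgeR. Among the largest changes, regions near Scg5 (chromosome 2, 113828619 to 113829624, at least 17.3-fold more accessible), Vmn2r3 (chromosome 3, 64259306 to 64260261, at least 16.4-fold) and Gm17622 (chromosome 13, 96496295 to 96497545, in Polk, at least 8.42-fold) had 0 control cut sites. Regions near Ccdc81 (chromosome 7, 89818161 to 89819081; ratio 52.4, 9.15 to 2093) and Gm29202 (chromosome 11, 95982187 to 95983127, by Igf2bp1; ratio 45.6) opened. Regions near Gm11817 (chromosome 4, 9440562 to 9441702, in Clvs1; -2.84, SE 0.23), Lypd8 (chromosome 11, 58398426 to 58399525; -2.69) and Gm31517 (chromosome 14, 15062323 to 15063638; -2.49) closed. Within 2500 bp of a gene start 1176 of 13975 regions were called, and 3299 of 21389 farther away. In a fit without the treatment term, 2268 regions passed without the CKO inhibitor and 2363 without the CKO vehicle library. Calls were lost for Gsn (adjusted p = 0.405) and Ccl2 (0.128) without the CKO inhibitor library. They were lost for Tcf21 (0.0871), Ccl2 (0.152) and Gm17622 (0.0757) without the control inhibitor library, and for Tcf21 (0.0761), Ccl2 (0.355) and Gm17622 (0.26) without the CKO vehicle library. Without the control vehicle library Gsn did not pass (0.0707) and Ccn1 did (0.0293). DESeq2 called 1134 regions and lost those of Amotl2 (0.0974), Ccl2 (0.444), Csf1r (0.0954), Fn1 (0.0598), Gsn (0.331) and Tcf21 (0.205). Gsn was also lost with library size scaling (0.054) and Gm17622 with doublets kept (0.196).

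Across 11776 genes with a region within 2500 bp of their start, the RNA and the accessibility log2 changes in fibroblasts correlated with a Spearman rho of 0.381 (0.288 within vehicle and 0.360 within inhibitor libraries). This is across genes, which are not independent replicates, so no p is given. Of the 2881 genes with higher RNA in CKO, 226 had a region called more and 22 a region called less accessible (median log2 change 0.07). Of the 2741 with lower RNA, 9 had one more and 367 one less accessible (median -0.20). Among the 6154 genes whose RNA did not pass, the numbers were 71 and 157 (median -0.05).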

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

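The exclusion of the sex mix as the whole cause was tested only after the result was seen, as were the differences between male and female nuclei. UMIs of the transgene sequences creERT and eGFP, which the comparisons do not use, were present in the CKO libraries. In the control libraries creERT was at 0 and eGFP had 3 UMIs with vehicle, 1 in the inhibitor multiome and 0 in the snRNA only library. The CKO inhibitor multiome library had 29 creERT and 64 eGFP UMIs, the CKO inhibitor snRNA only library 35 and 67, and the CKO vehicle library 23 and 42. Of the creERT UMIs, 65 were in fibroblasts (3.10 CPM) and 3 in endocardial nuclei.

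The difference between CKO and control changed with the inhibitor, by the interaction test, for 285 fibroblast, 97 macrophage, 72 cardiomyocyte and 66 vascular endothelial genes. It also differed between male and female nuclei of the same libraries, by an interaction test, for 1407 of 13585 fibroblast genes (572 with a higher and 835 with a lower signed log2 change in male nuclei), 4 macrophage genes, 67 cardiomyocyte genes and 74 vascular endothelial genes. For 84.3% of 6796 fibroblast genes called for genotype the fitted change went further in the direction of the call in male than in female nuclei. In that direction the median log2 change was 0.82 in male and 0.40 in female nuclei (6115 genes tested in both).

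Because the pools differed in their sex mix, the difference between male and female nuclei was weighed further: macrophages made up 26.1% of male and 10.7% of female nuclei in the CKO vehicle library, 6.5% and 3.12% in the CKO inhibitor multiome library and 6.61% and 2.91% in the CKO snRNA only library, against 6.56% and 6.15%, 1.05% and 1.5%, and 1.04% and 1.02% in the controls. Sex was also called on Xist and Y-linked counts thinned to 1000 UMIs per nucleus, leaving out nuclei below that depth. The lowest male over female ratio of the macrophage share in the CKO libraries was then 2.43. For that share only, this excludes unequal depth acting through the call of sex. Classes still came from unthinned counts, and the CKO nuclei called male stayed deeper. Their median UMIs were 3339 against 2919 with vehicle, 2914 against 2318 in the inhibitor multiome and 4430 against 3706 in the snRNA only library. An effect of depth on the naming of macrophages was not tested, and no gene fit was run on thinned nuclei. For the cluster 7 share of CKO fibroblasts, thinning lowered the ratio from 3.25 to 1.93 with vehicle. It fell from 2.37 to 1.67 in the inhibitor multiome and from 2.30 to 1.65 in the snRNA only library. The ratio of creERT in female over male CKO fibroblasts (25 and 29 UMIs) had a lower bound of 1.297. That bound excludes that female CKO mice lacked the Cre as a group, not that some of them did. A different sex mix as the whole cause of the fibroblast genes was excluded, since male nuclei alone and female nuclei alone each had at least 18.1% of the tested genes called. How much the mix adds cannot be told apart from genotype, since the median log2 change of the called genes in female nuclei was 0.566 times that with all nuclei, between the bounds set before. UMIs of the reporter sequence eGFP were not fewer in female than in male CKO fibroblasts (5.09 and 4.46 CPM, from 23 and 54 UMIs). The ratio was 1.141, with a counting interval of 0.668 to 1.89. This compares the sexes as groups, and measures neither single animals nor the Lats1 and Lats2 alleles. Sex and the single animals of a pool, which may differ in recombination as much as in sex, were not separable either, since nuclei were not assigned to animals.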

How the results depend on the processing

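Nuclei of 1 sex, cluster 7 or 15 left out, regions of like covered length and regions without each library and the treatment term were chosen after seeing the data. Of 212 named gene values, 90 kept direction and side of the threshold in every alternative that tested them and 31 changed sign in at least 1 of them. Of 26 named regions, 17 kept both and 1 changed sign. Over all alternatives other than a left-out library, 2107 gene values stayed, 213 were weaker and 47 changed sign. With a library left out, 1002 stayed, 85 were weaker, 1 was stronger and 21 changed sign. Of the 64 called genes named for fibroblast genotype, 49 kept their call in each setting that tested them, and 0 lost it when a library was left out. The call was kept in this way by 9 of 29 for macrophage genotype, 7 of 18 for cardiomyocytes, 4 of 14 for vascular endothelial nuclei and 0 of 17 for the inhibitor in fibroblasts. It was kept by 1 of 15 for the inhibitor in macrophages, 2 of 19 for the interaction and 13 of 20 for the regions. DESeq2 gave no adjusted p for 21 named values. The interaction and the planned region fit were not run without single libraries, since 0 residual degrees of freedom would be left. Smaller counts with equal nuclei per library (565 fibroblast, 95 macrophage, 94 cardiomyocyte and 111 vascular endothelial nuclei) and with fewer libraries come with fewer counts or degrees of freedom by construction. Nuclei of 1 sex alone also hold fewer UMIs by construction. Classes clustered per library gave endocardial nuclei of CKO libraries the vascular endothelial name, which changes what that class holds. For the other changes the cause was not tested.

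Fibroblast genotype genes (7346) were 4797 with DESeq2, 4672 with equal nuclei, 2221 in female nuclei and 3240 with cluster 7 left out. Without single libraries they ranged from 4500 to 7968. Macrophage genes (1319) were 709 with DESeq2, 463 with classes clustered per library, 833 with equal nuclei and 684 with no stratum term. They were 566 in the multiome libraries, 222 in male nuclei, 328 in female nuclei and 650 to 1518 without single libraries. Cardiomyocyte genes (627) were 294 with DESeq2, 962 with no filter, 1092 with doublets kept, 403 with at least 1000 genes per nucleus, 166 with equal nuclei and 221 with no stratum term. They were 1100 in the inhibitor libraries, 299 in the multiome libraries, 378 in male nuclei, 162 in female nuclei and 367 to 1096 without single libraries. Vascular endothelial genes (1143) were 377 with DESeq2, 339 with classes clustered per library, 296 with equal nuclei and 461 with no stratum term. They were 446 in the multiome libraries, 607 in male nuclei, 104 in female nuclei and 355 to 1716 without single libraries.

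Fibroblast genes for the inhibitor (85) were 31 with DESeq2, 41 with its size factors, 341 with no filter, 144 with doublets kept, 35 with at least 1000 genes per nucleus and 3 with equal nuclei. Without single libraries edgeR called from 0 (615 at an unadjusted p under 0.05) to 594. Macrophage genes for the inhibitor (76) were 26 with DESeq2, 208 with no filter, 169 with doublets kept, 1 with classes clustered per library, 44 with equal nuclei and 47 to 378 without single libraries. The interaction (285) gave 51 genes with DESeq2 and 163 with equal nuclei. Camera called 9 fibroblast and 5 macrophage lists for genotype and 2 macrophage lists for the inhibitor. With an estimated correlation it called 0 in each case. Fry called 10 fibroblast and 2 macrophage lists for genotype and 0 macrophage lists for the inhibitor, with p-values that shift with the arbitrary rotation of the residuals, and without single libraries camera called 1 to 6 of the latter. Regions (4475) were 1134 with DESeq2 and 2268 to 6067 without single libraries. The correlation of RNA and accessibility (rho 0.381) was 0.288 in vehicle and 0.360 in inhibitor libraries. Without single libraries the share of macrophages differed by 3.70 to 8.36 points and that of fibroblasts by -10.6 to -9.27 points.

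With cluster 7 left out, Lats2 was at a log2 change of -0.037, Csf1 at -0.28, Bmp6 at -0.528, Bmp4 at -0.164 and Wwtr1 at 0.251 in fibroblasts. Wwtr1 (-0.01) was also at 0.012 with DESeq2, 0.012 with its size factors, 0.002 with no filter, 0.045 with equal nuclei, 0.012 with free RNA left out, 0.003 in the multiome libraries and 0.03 in female nuclei. Without single libraries Wwtr1 ranged from -0.021 to 0.018. Egr1 was at 0.113 in male nuclei. For the inhibitor in fibroblasts, equal nuclei put Lats2 at 0.016 and Wwtr1 at -0.065. Without single libraries Lats2 ranged from -0.174 to 0.166, Hmga2 from -3.468 to 3.379 and Col2a1 from -2.364 to 0.334. For the interaction, equal nuclei put Yap1 at 0.071 and Wwtr1 at 0.178, doublets kept put Wwtr1 at 0.015, and classes clustered per library put Neil3 at -3.579 and Mki67 at -5.389.

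In macrophages, classes clustered per library put Lats1 at -0.024, Wwtr1 at -1.139 and Csf1r at 0.044 for genotype and Csf1 at -0.391 for the inhibitor. Without single libraries the genotype values ranged from -0.008 to 0.141 for Lats1 and from -0.082 to 0.488 for Wwtr1. For the inhibitor they ranged from -0.881 to 0.042 for Wwtr1 and from -0.186 to 0.079 for Csf1r. Equal nuclei put Lats2 at -0.032 and Csf1 at -0.628, and doublets kept put Wwtr1 at 1.037, for the inhibitor. In cardiomyocytes female nuclei put Wwtr1 at 0.006, Tcf21 at -0.167 and Ankrd1 at -0.66, and doublets kept put Tcf21 at -0.243.

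In vascular endothelial nuclei, classes clustered per library put Lats1 at 0.174, Yap1 at 0.171, Wwtr1 at 0.082, Csf1 at 0.434, Aspm at -0.174, Tpx2 at -0.521 and Kif11 at -1.295. Female nuclei put Lats1 at 0.008, Yap1 at 0.002 and Csf1 at 0.254. Equal nuclei put Wwtr1 at 0.002 and Csf1 at 0.164. The multiome libraries put Lats1 at 0.13 and Csf1 at 0.122, DESeq2 put Lats1 at 0.004, and the inhibitor libraries put Wwtr1 at 0.01. Without single libraries the ranges were -0.228 to 0.131 for Lats1, -0.175 to 0.011 for Wwtr1 and -0.214 to 0.122 for Csf1. The region named for Csf1 was at 0.034 when scaled by library size. Control macrophages numbered 95 to 152 nuclei per library, and with 95 in every library 833 macrophage genes were called.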

Other observations

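The tests of Hcn4 against node cells, of the clock genes, of the sex mix as the whole cause for Zbtb16 and of the other splits were chosen only after the result was seen; the rest were written before. Endocardial nuclei, outside the planned comparisons and, like mesothelial nuclei, not tested by sex, had 1595 genes higher and 1492 lower in CKO of 15700 tested (edgeR adjusted p under 0.05, 3 libraries per genotype). The adhesion genes Selp (log2 change 5.70) and Sele (4.31) and the chemokine gene Ccl2 (4.61) rose, and so did Itih4 (5.71), Ch25h (5.56), Pdgfa (4.03), Serpina3n (3.71) and Lrg1 (3.69), while Zbtb16 (-2.85), Klhl1 (-2.66) and Fam107a (-2.65) fell. Endocardial cluster 2 held 29.7% to 49.6% of the CKO and 0.34% to 3.07% of the control endocardial nuclei. Its name rests on a score of 2.16 for endocardial against 2.10 for vascular endothelial markers, near the margin of 0.05, and Selp, Sele, Ccl2, Itih4 and Lrg1 are among its 10 top genes, so these rises need not be those of endocardial nuclei. In the CKO libraries it took 41.6% of male and 20.5% of female endocardial nuclei with vehicle, 72.3% and 8.17% with inhibitor in the multiome library and 79.0% and 12.3% in the snRNA only library.

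Mesothelial nuclei had 408 genes higher and 206 lower in CKO of 13970 tested. Among the genes that rose were Ifi202b at 389 against 0 UMIs (at least 105-fold higher), Iigp1 (4.19), Gbp10 (4.14), Gbp2b (3.75), Tgtp2 (2.52), Serpina3n (5.19), Prg4 (4.04), Ccl2 (3.99), Thbs1 (3.57) and Lox (2.79), while Arnt2 (-2.20), Clec3b (-2.17) and Klf15 (-1.90) fell. In both classes these genes were picked after their values were seen.

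Hcn4, a channel gene of pacemaker cells, was higher in CKO cardiomyocytes. More sinoatrial node cells among the CKO cardiomyocytes remain a candidate explanation, as the 5 node genes had a median log2 change of 1.831. Of them Isl1 (3.98), Shox2 (2.67) and Tbx3 (1.42) passed, and Smoc2 (1.83, adjusted p = 0.065) and Tbx18 (0.68, 0.63) did not. Whether Hcn4 changed within atrial cardiomyocytes is left open.

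Zbtb16 and Fkbp5, genes that glucocorticoids induce, were lower together in CKO fibroblasts (-3.55 and -1.66), macrophages (-3.07 and -2.43) and cardiomyocytes (-1.59 and -1.29), whereas in vascular endothelial nuclei Zbtb16 fell by 3.58 and Fkbp5 rose by 0.57. By sex, Fkbp5 was at 1.27 (adjusted p = 0.00113) in male and -0.26 (0.797) in female vascular endothelial nuclei, at -0.59 (0.422) and -2.39 (3.86e-05) in macrophages and at -1.22 (0.0723) and -1.11 (0.0198) in cardiomyocytes. The sex mix as the whole cause was excluded for Zbtb16, whose smallest fall in nuclei of 1 sex was -1.166 and passed in all 4 classes, though the pair kept 0.72 of its change in male and 0.87 in female nuclei, and 0.72 missed the bound of 0.75 set before. Less glucocorticoid signalling may contribute: other responsive genes had medians of -1.33, 0.155, -0.147 and -0.174 in fibroblasts, macrophages, cardiomyocytes and vascular endothelial nuclei, and while 3 of these lie above the bound against it, none does so by more than its standard error (0.672, 0.35 and 0.316), so the test could not decide. Another time of day at collection stays open too, since morning and evening clock genes differed by 0.416, 0.647, 0.826 and 1.644, neither all small nor mostly large.

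Other splits of the 6 libraries into 3 and 3 were counted for the genotype comparisons. Of the 10 splits per class, 1, the real split, called as many fibroblast, macrophage, cardiomyocyte or vascular endothelial genes, and the highest other split called 0. For the fibroblast lists the real split called 9 lists and the highest other 8 (1 split as large), and for the macrophage lists the real split called 5 and the highest other 6 (3 splits as large). The splits with 8 and 6 lists leave 2 strata undivided and were tested over more genes (16592 in place of 15729 and 11681 in place of 10748). Of the 3 other splits that part every stratum like the real one, the highest called 5 fibroblast and 4 macrophage lists. With 10 splits there are too few for a share under 0.05. A false split also leaves the genotype difference in the residual spread, which lowers its gene calls, so the 0 does not measure chance.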
